A study of Mus musculus with 10 samples.

How the data were processed

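Polyadenylated RNA from mouse placenta was sequenced on 10 libraries, 5 from animals given Fusobacterium nucleatum (Fn), a Gram-negative anaerobe of the mouth, and 5 from animals given saline (PBS). Per the labels' protocols, RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads, and libraries were made with an NEBNext Ultra kit and amplified by PCR. The labels give wild type placenta, the treatment and a replicate number. They give no gestational day, dose, route, dam or litter, and do not say whether the replicates were separate animals, so p-values measure the spread between these samples, which may in part be technical.

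The authors deposited a table of estimated counts per Ensembl gene, in which 91.5% of the values were whole numbers, and FPKM values (scaled for transcript length and library depth) for the same libraries. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, with no role or order. The genome build and the use of strand are not given in the sources used here, so no coordinates are printed, and near-identical, overlapping or antisense genes are treated as uncertain because the counting could divide their reads. The table's control columns were taken as the PBS libraries of the same number, since PBS is the only group not given Fn. Of 22322 gene identifiers in the table, 22267 were in the GENCODE M21 name table. Symbols came from the deposited table, and 20 symbols stood on more than 1 identifier.

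Total counts per library ranged from 20029190 to 27206445. Counts were rounded to whole numbers, which moved no library total by more than 9.8e-05%. Genes were filtered with edgeR's filterByExpr (minimum count 10), which kept 14380 of 18934 genes with any count. Libraries were scaled by TMM and compared with edgeR 4.0.16's quasi-likelihood test (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. All 10 libraries entered the fit with no covariate. The biological coefficient of variation was 18.0%. Confidence intervals of fold changes are 95% intervals from the fit.

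Before the data were examined, 30 gene lists were fixed: 13 cell type marker lists, 16 pathway lists and 1 list of Y-linked genes used as a technical control. Of their 533 symbols, 529 were in the table. The 29 lists other than the Y-linked one were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, adjusted over the 29 lists. The same test with a correlation estimated from the residuals, fry, and an exact two-sided permutation test of the list score (mean log2 CPM of the members, 252 divisions of the libraries) stand beside it. With 5 against 5 libraries the smallest p that the exact test can give is 0.00794. Correlations across the 10 libraries used 100000 permutations.

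The rule for named genes was also fixed before the data were examined. Since fewer than 10 genes passed the threshold, it took the 10 genes with the smallest p in each direction, reported as not passing. It added 15 genes named in advance for their roles in vessel growth, inflammation, hypoxia and trophoblast (Flt1, Pgf, Vegfa, Eng, Il1b, Il6, Tnf, Cxcl1, Tlr2, Tlr4, Hif1a, Tpbpa, Prl3b1, Gcm1 and Prl8a2), and the 4 members with the smallest p of each list that passed camera. Other members of a list that are named were chosen after their values were seen.

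The gene test was tested on simulated data drawn for 14278 genes from the means and library sizes of this comparison. It recovered 31 of 67 genes changed 1.5-fold, 48 of 67 changed 2-fold and 60 of 66 changed 4-fold, with 6 false calls among 145, and made 0 calls on data with no change. In the same simulation DESeq2 recovered 154 changed genes with 49 false calls. The list test recovered both lists that had been shifted 1.5-fold, with 1 other call, and made 0 calls with no change. The simulated genes varied independently of each other. Members of the called lists varied together in the real libraries (estimated correlation from 0.088 for immediate early genes to 0.790 for yolk sac markers). The simulation therefore does not show how often the preset correlation calls a list by chance here. Over all tested genes, the first principal component of the real libraries held 41.3% of the variance. Rates of false and recovered gene calls in the simulation thus need not hold for these libraries.

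The alternatives for genes were RLE and upper quartile scaling, 2 other filters, DESeq2 1.42.0, limma voom with and without quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), covariates for Y-linked expression, decidual markers and 1 surrogate variable (sva 3.50.0), the replicate number as a block, a 2-fold minimum and the omission of each library. For lists they were the estimated correlation, fry, RLE, genes with any count, and the same block, covariates and omissions. The first principal component as a covariate, and the surrogate variable for lists, were added after seeing the data. Within each group every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 16.7 to 116 over 20 pairs), so no library was counted as a repeat of another. The list symbols absent from the table (Ahsp, Crry, H19 and Meg3) were not analysed here.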

Results

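Gene expression was measured by RNA sequencing in the placentas of mice treated with Fusobacterium nucleatum (Fn, 5 libraries) or saline (PBS, 5 libraries) during pregnancy. The series asks how this bacterium, whose presence in the placenta has been linked to complications such as preeclampsia, affects placental gene expression. Total counts per library averaged 22423600 ± 3063420 in PBS and 22273400 ± 1652510 in Fn libraries (SD, n = 5 each), with a range over all libraries from 20029190 to 27206445 counts. The share of mitochondrial counts was 3.86 ± 0.123% in PBS and 3.95 ± 0.229% in Fn libraries, which did not differ by an exact permutation test (two-sided p = 0.492).

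The first principal component held 41.3% of the variance and did not separate the treatments. PBS libraries lay at -34.3, -25.8, -20.6, 20.4 and 28.2 along it, and Fn libraries at -30.8, 35.7, 20.7, 4.37 and 2.01 (exact two-sided permutation p = 0.452). Libraries of both treatments therefore stood at each end. Markers of labyrinth, spongiotrophoblast and uterine natural killer cells were high at the negative end. The labyrinth transcription factor Gcm1 ranged from 0.533 CPM in Fn replicate 2 to 21.6 CPM in Fn replicate 1.

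**Figure D1:**
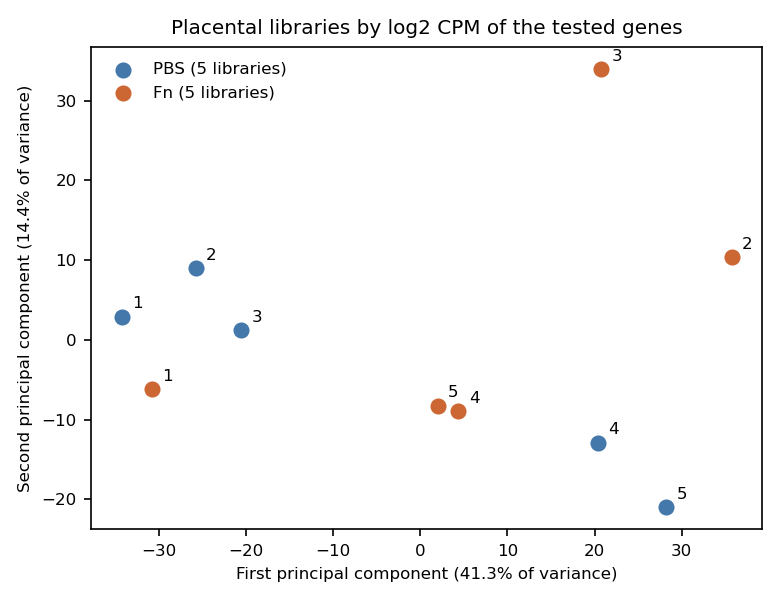
Positions of the 10 placental libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, each point 1 library with its replicate number, blue for PBS and orange for Fn. PBS replicates 1 to 3 and Fn replicate 1 lie at the negative end of the first component, which holds 41.3% of the variance, and PBS replicates 4 and 5 lie at the positive end with Fn replicates 2 and 3.

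Fn and PBS placentas were compared gene by gene. No single gene passed the threshold, so the account rests on small differences and on groups of genes. Of 14380 genes tested, 0 were called higher and 0 lower in Fn by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.99976. At an unadjusted p under 0.05 there were 310 genes higher and 236 lower in Fn, 546 in all, where chance alone gives about 719. Across other settings this count lay on both sides of the chance number, from 415 without Fn replicate 3 to 1009 without Fn replicate 1, with 945 for the first component as a covariate and 960 for voom with quality weights. limma voom, with or without quality weights, and limma on FPKM also called 0 genes, and DESeq2 called 4. The expression of 91 genes (0.633%) did not overlap between the treatments, and chance gives 0.794%. The median standard error of a log2 fold change was 0.11. For 13049 genes (90.7%) the 95% interval excluded a change of 2-fold or more, and for 10675 (74.2%) a change of 1.5-fold or more, so that larger changes of the remaining genes could not be excluded at this number of libraries.

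The gene with the smallest p was Sele (ENSMUSG00000026582), which encodes E-selectin, an adhesion molecule of activated endothelium. It measured 20.9 ± 1.07 CPM in PBS and 15.9 ± 1.07 CPM in Fn libraries (SD, n = 5 each), a log2 fold change of -0.39 (SE 0.068), and was lower in every Fn library than in any PBS library. Its adjusted p was 0.99976 with edgeR and 0.00476 with DESeq2. DESeq2 also called Duox1 (ENSMUSG00000033268), an NADPH oxidase that makes hydrogen peroxide, at 3.78 ± 1.75 CPM in PBS and 1.24 ± 0.490 CPM in Fn (log2 fold change -1.60, adjusted p = 0.0421). Its other calls were the predicted genes Gm43951 (log2 fold change -3.07, adjusted p = 0.00476) and Gm14308 (3.44, adjusted p = 0.0421). Gm14308 averaged 0.113 CPM in PBS and 1.20 CPM in Fn libraries and belongs to a family of closely similar zinc finger genes, so its counts are uncertain. Under the alternatives other than DESeq2 the smallest adjusted p was 0.451 for Sele, 0.706 for Duox1, 0.176 for Gm43951 and 0.144 for Gm14308.

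Among the 10 genes with the smallest p that were higher in Fn, none of which passed edgeR's test, were Adm (ENSMUSG00000030790), which encodes the vasodilator adrenomedullin, at 79.8 ± 6.28 CPM in PBS and 97.7 ± 4.97 CPM in Fn (log2 fold change 0.29, SE 0.063), and Dusp5, a phosphatase of the ERK kinases, with a log2 fold change of 0.37 (SE 0.087). Nr4a1, an immediate early nuclear receptor, had 0.61 (SE 0.15), the leukotriene receptor Cysltr2 0.55 (SE 0.14), and the D-type cyclin Ccnd3 0.28 (SE 0.070). The others were Gm13889 (0.79), Tmem189 (0.23), Gm29666 (1.16), 4930486L24Rik (0.51) and Gm14308. Reads of Tmem189 cannot be fully separated from its read-through neighbour Ube2v1. On the lower side, besides Sele, Duox1 and Gm43951, stood Plau, the urokinase plasminogen activator (log2 fold change -0.25, SE 0.063), the guidance cue Ntn1 (-0.21, SE 0.054), the matricellular protein Postn (-0.30, SE 0.080), Apbb1ip (-0.42), the ubiquitin ligase Nedd4l (-0.24), Zbtb32 (-0.93) and Slc25a40 (-0.25). All 20 had an edgeR adjusted p of 0.99976.

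Genes of vessel growth that are often studied in preeclampsia showed no difference larger than the spread between libraries. Flt1, a receptor of vascular endothelial growth factor, measured 2179 ± 646 CPM in PBS and 1807 ± 804 CPM in Fn (log2 fold change -0.27, 95% interval -0.91 to 0.37). It stood at 2490 to 3144 CPM in PBS replicates 1 to 3 and Fn replicate 1, the negative end of the first component, and at most 1919 CPM in the other libraries. The log2 fold change was 0.079 for Pgf, a ligand of Flt1 (95% interval -0.31 to 0.47), -0.12 for Vegfa (-0.61 to 0.36) and 0.16 for Eng (-0.29 to 0.60). Hif1a, the oxygen-regulated transcription factor, had -0.050 (95% interval -0.18 to 0.081). Of the 23 measured angiogenic factors and receptors 14 were higher and 9 lower, with a mean of -0.0088. None was called over all genes, and Adm alone was called when edgeR's p was adjusted over the list alone (adjusted p = 0.0157).

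Inflammatory genes gave no common direction. Il1b, a cytokine of activated macrophages, had a log2 fold change of 0.62 (SE 0.24) at only 1.03 ± 0.285 CPM in PBS and 1.58 ± 0.376 CPM in Fn. The log2 fold change was 0.72 (SE 0.46) for Tnf, 0.16 (SE 0.51) for the chemokine Cxcl1, -0.062 (SE 0.17) for Tlr2 and 0.044 (SE 0.19) for Tlr4, the receptor of lipopolysaccharide. Il6 had 1 to 5 counts per library and was too low to test. Of 22 measured genes of Toll-like receptor and NF-kB inflammation 10 were higher and 12 lower, with a mean of 0.018 (camera adjusted p = 0.990), and of 11 chemokines 6 were higher and 5 lower (mean -0.014, adjusted p = 0.990).

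The gene lists were then compared between Fn and PBS. With the preset correlation, camera called 7 of 29 lists, 3 higher (immediate early genes, neutrophil markers and yolk sac endoderm markers) and 4 lower (cell cycle, spongiotrophoblast, interferon response and unfolded protein response). With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05. fry also called 0, with 1 at an unadjusted p under 0.05, and the exact permutation test of list scores called 0, again with 1. That list had the smallest p the exact test can give (0.00794), which became 0.230 after adjustment over the 29 lists. The exact test thus could not call 1 list alone, so its lack of a call does not count against that list, the immediate early genes. The other lists called by camera had an unadjusted exact p from 0.103 (neutrophils) to 0.540 (interferon response). Their score differences thus lay within the spread between libraries by this test. With the first component as a covariate camera called 8 lists with the preset correlation, of which 3 were among the 7. Over all genes 0 of 480 list members were called. Adjusted over the list alone, 1 member was called in each of 4 lists, namely Nr4a1, S100a8, Adm and Postn, an adjustment that makes no allowance for the 29 lists. Over the alternatives that change 1 choice the adjusted p reached from 5.6e-11 to 0.0769 for immediate early genes, and up to 0.996 for each of the other called lists, from 5.7e-07 for cell cycle, 5.5e-06 for neutrophils, 3.3e-06 for yolk sac, 5.0e-07 for interferon and 7.8e-05 for spongiotrophoblast and the unfolded protein response.

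Immediate early genes, which are transcribed within minutes of a stimulus, were the group with the smallest p. All 19 measured members were higher in Fn, with a mean log2 difference of 0.29 and a median of 0.20 (camera adjusted p = 7.0e-09, and adjusted p = 0.0769 with an estimated correlation). The list score was 4.48 ± 0.104 in PBS and 4.77 ± 0.125 in Fn libraries (mean log2 CPM, SD, n = 5 each), every Fn library lying above every PBS library. The exact two-sided permutation p was 0.00794, the smallest it can give, and 0.230 after adjustment over the lists, so this test could not call 1 list alone. Fosb, a partner of the AP-1 transcription factor, measured 3.55 ± 0.678 CPM in PBS and 7.03 ± 4.78 CPM in Fn (log2 fold change 0.98, SE 0.35, but 0.46 without Fn replicate 5, which measured 15.6 CPM), Fosl1 had 0.65 (SE 0.24), and the MAP kinase phosphatase Dusp1 0.37 (SE 0.11). Nr4a1 measured 9.13 ± 1.58 CPM in PBS and 13.9 ± 2.39 CPM in Fn. It was called only when edgeR's p was adjusted over the list alone (adjusted p = 0.0280), not over all genes (0.99976). Camera called the list with each of the 10 libraries left out, at mean differences of 0.24 to 0.32. With an estimated correlation it was called in 1 of 13 further settings, chosen after the results were seen, namely with the decidual markers as a covariate (mean 0.33, camera adjusted p = 0.0387), and not with the first component as one (0.294) or with any library left out (0.0893 to 0.329).

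**Figure D2:**
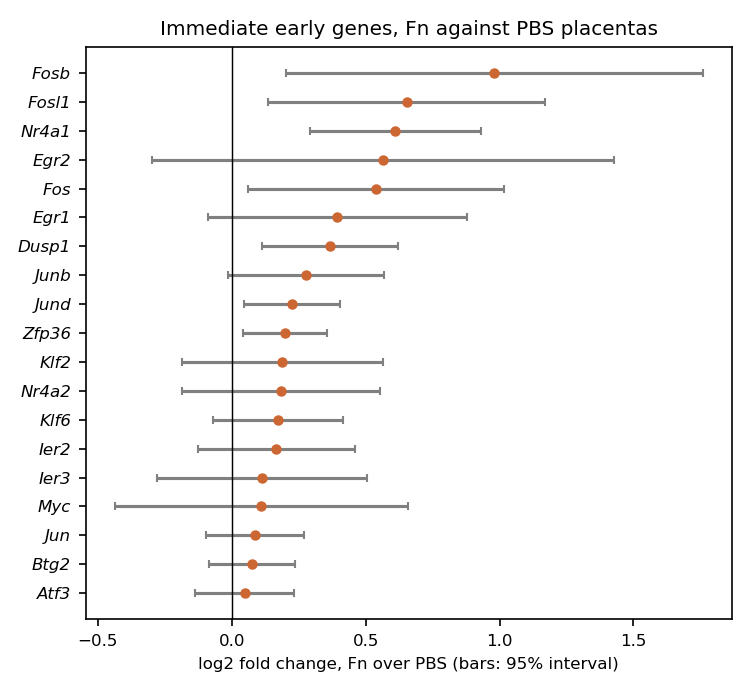
log2 fold change of Fn over PBS (horizontal axis) for the 19 measured immediate early genes, 1 gene per line, with 95% intervals from edgeR's fit as bars. All 19 points lie above 0, from Atf3 (0.048) to Fosb (0.98), and the intervals of 7 genes exclude 0.

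Genes of the fixed cell cycle list were lower. Of 22 measured members 21 were lower in Fn, with a mean log2 difference of -0.21 (camera adjusted p = 3.4e-05, and adjusted p = 0.996 with an estimated correlation), and Pcna alone was higher (0.053). The mitotic kinase Aurka had a log2 fold change of -0.45 (SE 0.14), the spindle motor Kif11 -0.48 (SE 0.22), the kinetochore motor Cenpe -0.40 (SE 0.19) and cyclin Ccna2 -0.40 (SE 0.21), none of them called over the list alone. The list score followed the first principal component over the 10 libraries (r = -0.87, rho = -0.88, adjusted permutation p = 0.000546 and 0.00354, r = -0.82 without the 2 libraries farthest from the median). The mean difference shrank to -0.11 without PBS replicate 1 and to -0.14 without Fn replicate 2, and was -0.11 with the first component as a covariate, and the call was kept in each (camera adjusted p = 0.0308, 0.00291 and 0.0341) with the preset correlation but in none with an estimated one (0.996, 0.980 and 0.800). Without PBS replicate 1 Kif11 had -0.31 and Ccna2 -0.25. The broader cell cycle pathway in the deposited table's annotation (120 genes) did not differ. Its mean was -0.018 (camera adjusted p = 0.993 with the preset correlation), so the difference was limited to the fixed list.

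Neutrophil markers were higher, with 8 of 11 measured members higher in Fn and a mean log2 difference of 0.58 (camera adjusted p = 0.0136, and adjusted p = 0.996 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, was called over the list alone (edgeR adjusted p = 0.0431), at 11.3 ± 1.31 CPM in PBS and 15.3 ± 2.51 CPM in Fn. The iron-binding proteins Ltf and Lcn2, which epithelia also make, had log2 fold changes of 1.43 (SE 0.50) and 1.04 (SE 0.53, but 0.60 for Lcn2 without Fn replicate 3), and the chemokine receptor Cxcr2 had -0.13 (SE 0.064). In Fn replicates 2 and 3 Lcn2 measured 147 and 172 CPM and Ltf 149 and 112 CPM, and in the other Fn libraries at most 41.4 and 71.5 CPM. The call was lost without PBS replicate 1, PBS replicate 3 or Fn replicate 3 (means 0.49, 0.46 and 0.43, camera adjusted p = 0.0502, 0.0713 and 0.0688), with the first component as a covariate (0.51, adjusted p = 0.0642) and with the decidual markers as one (0.51, 0.0551).

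Spongiotrophoblast and glycogen cell markers were lower in Fn for 14 of 15 members, with a mean of -0.25 (camera adjusted p = 0.0287, and adjusted p = 0.996 with an estimated correlation). Tpbpa, the classical marker, measured 14430 ± 4083 CPM in PBS and 12275 ± 4993 CPM in Fn (log2 fold change -0.23, SE 0.27), Pcdh12 had -0.30 (SE 0.24), Aldh1a3 -0.74 (SE 0.62), Psg17, from a family of similar genes, -0.38 (SE 0.31), and the connexin Gjb3 0.14 (SE 0.095, but 0.066 without Fn replicate 3). Yolk sac and fetal liver type endoderm markers were higher for 16 of 17 members, with a mean of 0.40 (camera adjusted p = 0.0235, and adjusted p = 0.996 with an estimated correlation). Among these the endocytic receptors Lrp2 and Cubn had 0.25 (SE 0.30) and 0.26 (SE 0.33), the thyroid hormone carrier Ttr 0.21 (SE 0.26) and Apom 0.31 (SE 0.43). Both lists followed the first component (spongiotrophoblast r = -0.96, rho = -0.89, adjusted permutation p = 0.000455 and 0.00354, r = -0.94 without the 2 farthest libraries, and yolk sac r = 0.79, rho = 0.77, adjusted permutation p = 0.0164 and 0.0239, r = 0.81). With the component as a covariate their means were -0.065 and 0.11 and both calls were lost (camera adjusted p = 0.431 for each). The spongiotrophoblast call was also lost with the decidual markers as a covariate (mean -0.13, adjusted p = 0.472) and without any of PBS replicates 1 to 3 or Fn replicates 2 to 5 (adjusted p = 0.0634 to 0.414), with means of -0.42 to -0.13 over all single omissions, and the yolk sac call without any of PBS replicates 1 to 3 or Fn replicates 2, 4 and 5 (0.0794 to 0.624), with means of 0.16 to 0.71.

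Interferon response genes were lower for 14 of 22 members with a mean of only -0.084 (camera adjusted p = 0.0287, and adjusted p = 0.996 with an estimated correlation). The antiviral genes Oas1a, which has close paralogs, and Oas2 had log2 fold changes of -0.21 (SE 0.096) and -0.32 (SE 0.17), Stat2 had -0.15 (SE 0.077) and Isg15 -0.19 (SE 0.12), with Oas2 at -0.20 without PBS replicate 5 and Isg15 at -0.11 without Fn replicate 5. The call was lost without PBS replicates 4 or 5 or Fn replicates 1 or 5 (adjusted p = 0.207 to 0.769), and without Fn replicate 1 the mean was 0.015. With the first component as a covariate the mean was -0.19 (camera adjusted p = 5.0e-07 with the preset correlation and 0.444 with an estimated one). Genes of the unfolded protein response were lower for 11 of 17 members with a mean of -0.12 (camera adjusted p = 0.0340, and adjusted p = 0.996 with an estimated correlation). Its members with the smallest p were Trib3 (-0.77, SE 0.23) and the asparagine synthetase Asns (-0.49, SE 0.17), both targets of the amino acid response as well, then the sensor Ern1 (-0.15, SE 0.088) and Xbp1 (-0.088, SE 0.064). That call was lost with the first component as a covariate (mean -0.031, camera adjusted p = 0.666), with the decidual markers as one (mean -0.074, 0.361), with genes of any count (mean -0.11, 0.0517) and without any of PBS replicates 1 to 3 or Fn replicates 2, 3 and 5 (0.0998 to 0.413), with means of -0.23 to -0.065 over all single omissions. The interferon score followed the first component with r = 0.80 and rho = 0.73 (adjusted permutation p = 0.00957 and 0.0309, r = 0.79 without the 2 farthest libraries), and the unfolded protein score with r = -0.88 and rho = -0.82 (0.00310 and 0.0124, r = -0.82), among 13 relations computed.

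**Figure D3:**
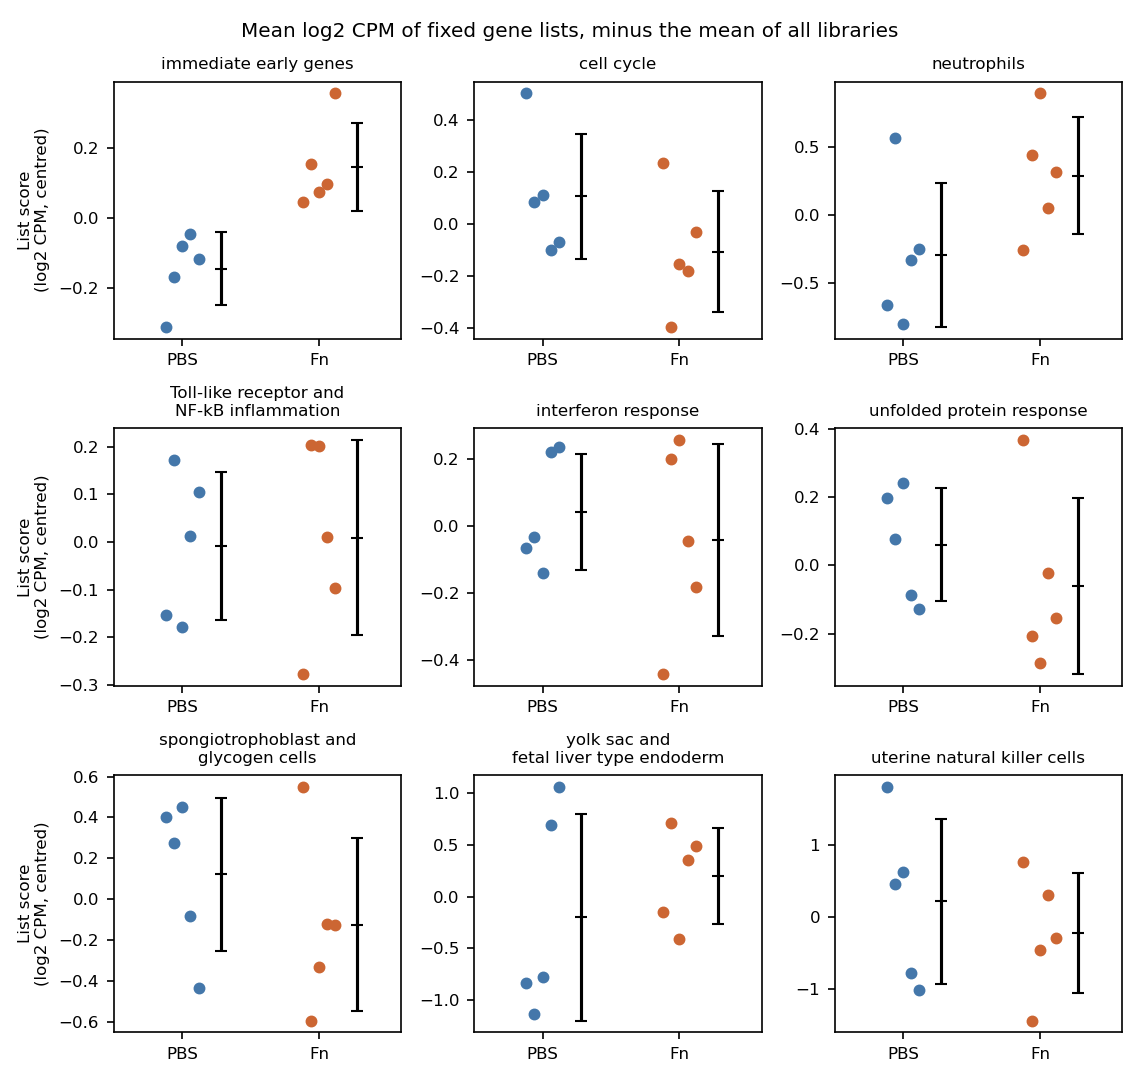
List scores of 9 fixed gene lists, as mean log2 CPM of the members minus the mean over all 10 libraries (vertical axes, scaled separately), with 1 point per library, blue for PBS and orange for Fn, and black bars for mean and SD (n = 5 each). The treatments do not overlap for immediate early genes and overlap for the other 8 lists.

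The remaining lists did not pass in the fit of all 10 libraries by treatment, and several were called in other settings. Decidual stroma markers were higher for 12 of 17 members (mean 0.11, camera adjusted p = 0.0572, but 0.0485 with RLE scaling and 0.0258, 0.0264 and 0.0122 without PBS replicate 1, PBS replicate 5 or Fn replicate 4, and 0.273 without Fn replicate 2 at a mean of 0.065), with Prl8a2 at 1194 ± 106 CPM in PBS and 1448 ± 257 CPM in Fn (log2 fold change 0.28, SE 0.12). Uterine natural killer cell markers, largely granzymes of a family of similar genes, were lower for 8 of 9 members with a mean of -0.44 (adjusted p = 0.253). That mean was -0.045 without PBS replicate 1, -0.15 without Fn replicate 2, -0.67 without PBS replicate 4 and -0.73 without PBS replicate 5 (adjusted p = 0.987, 0.729, 0.0330 and 0.0118), -0.69 without Fn replicate 1 (0.0953), and 0.0063 with the first component as a covariate (0.945). Labyrinth markers had a mean of -0.087 (adjusted p = 0.990), with Gcm1 at -0.46 (SE 0.93), but with the first component as a covariate the list turned higher in Fn and was called (mean 0.13, adjusted p = 0.0302). Trophoblast giant cell markers had a mean of -0.016 (adjusted p = 0.990), with the placental lactogen Prl3b1 at -0.12 (SE 0.13). Erythroid genes were lower for 12 of 13 members (mean -0.26, adjusted p = 0.137). Their mean was -0.048 without PBS replicate 2 and -0.15 without PBS replicate 3 (adjusted p = 0.980 and 0.652), and they were called without PBS replicate 4, PBS replicate 5 or Fn replicate 5 (means -0.50, -0.56 and -0.42, adjusted p = 0.00908, 0.000259 and 0.0189). With the first component as a covariate the erythroid mean was -0.063 (adjusted p = 0.707). Antigen presentation genes were lower for 14 of 18 (mean -0.11, adjusted p = 0.212, but -0.045 and 0.909 without Fn replicate 5), and were called with the first component or the decidual markers as a covariate (means -0.15 and -0.17, adjusted p = 0.0355 and 0.0396). The means were 0.050 for oxidative stress (adjusted p = 0.343) and 0.046 for apoptosis and inflammatory cell death (0.518), and over single left-out libraries they ran from 0.025 to 0.083 and from 0.0089 to 0.10. For matrix and matrix proteases the mean was 0.030 (adjusted p = 0.975). The other lists all had a camera adjusted p of 0.990, with means of -0.055 for uterine smooth muscle, 0.0025 for macrophages and monocytes, -0.026 for T and B lymphocytes, 0.0058 for endothelial cells, -0.010 for fetal pericytes and mesenchyme, 0.033 for complement and coagulation, -0.0088 for angiogenic factors, -0.0078 for hypoxia and glycolysis, -0.036 for imprinted growth genes, 0.017 for nutrient transporters and 0.054 for steroid hormone synthesis and receptors. With the first component as a covariate macrophages (mean -0.14, camera adjusted p = 0.0329), hypoxia (0.074, 0.0355) and nutrient transporters (0.067, 0.0355) were called as well, and the sign had turned for macrophages and hypoxia. Without PBS replicate 5 uterine smooth muscle was called higher (mean 0.13, adjusted p = 0.0118). All calls in this paragraph rest on the preset correlation of 0.01. With an estimated one, which for labyrinth was 0.357 in the fit by treatment and 0.204 with the first component as a covariate, none of these lists was called in the same settings. Mean, median and test did not share a sign for trophoblast giant cells, macrophages, Toll-like receptor genes, complement, angiogenic factors, matrix and imprinted genes, none of which was called without a covariate.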

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

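Of 186 groups of 5 values that the text reports, 9 held a library whose gap to its nearest neighbour exceeded 0.71 of the group's range, and chance alone gives about 9.3. No test in this part was chosen after its result was seen, and no explanation was tested for these values, which are in log2 CPM.

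Uterine smooth muscle markers stood at 6.77 in PBS replicate 5 against 5.77 to 5.90 in the other PBS libraries (gap over range 0.870). T and B lymphocyte markers stood at 0.93 in PBS replicate 1 against -0.19 to 0.099 (0.744). Endothelial markers were low in PBS replicate 3, at 5.59 against 5.74 to 5.77 (0.861). The cyclin gene Ccnd3 was low in Fn replicate 4, at 5.40 against 5.68 to 5.76 in the other Fn libraries (0.777). Pgf was high in PBS replicate 3, at 4.91 against 4.43 to 4.54 (0.753). Tpbpa was high in Fn replicate 1, at 14.36 against 13.08 to 13.39 (0.759). Ltf was low in PBS replicate 3, at 2.78 against 4.71 to 5.49 (0.712). Ccna2 was high in PBS replicate 1, at 2.71 against 2.02 to 2.19 (0.752). Fosb was high in Fn replicate 5, at 3.97 against 2.14 to 2.44 (0.835).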

How the results depend on the processing

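The first principal component as a covariate, the surrogate variable for lists, and the settings below that add an estimated correlation to another change were chosen after seeing the data. The surrogate variable and the first component are in effect 1 covariate (r = 0.999678), so their agreement is no independent support. DESeq2 called 4 genes where edgeR called 0 (546 at an unadjusted p under 0.05), and in the simulated comparison DESeq2 made 49 false calls. Every other setting for genes, the omission of each library included, called 0. For lists, 7 calls became 0 with an estimated correlation and 0 with fry, which allow for members that vary together. With an estimated correlation, 0 lists were called with the first component, RLE or any library left out, and 1, immediate early genes, with the decidual covariate (adjusted p = 0.0387). Leaving out 1 library gave 3 to 10 called lists, with 4 without PBS replicates 1 or 2 or Fn replicates 2, 3 or 5, and 3 without PBS replicate 3, and the cause was not tested. The Y-linked covariate kept all 7 lists and genes with any count kept 6 of them. RLE kept 7 and added decidual stroma (adjusted p = 0.0485), and the decidual covariate kept 4 and added antigen presentation (0.0396). The first component and the surrogate variable each called 8 lists, of which only 3 (immediate early genes, cell cycle and interferon response) were among the 7, and the other 5 were labyrinth, macrophages, antigen presentation, hypoxia and nutrient transporters. Same-numbered Fn and PBS libraries did not deviate together as a set (r = -0.36 to 0.58, median 0.022, and 2 of 5 Fn libraries correlated best with their own number). No pairing by number was thus seen, but 5 such correlations cannot exclude one. With the replicate block the counts were 0 genes and 7 lists, and Tlr4 had -0.0092.

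Some genes named in advance, none past the threshold in any setting, changed sign, and the cause was not tested. With voom and quality weights the log2 fold changes were -0.037 for Pgf, -0.017 for Cxcl1 and 0.0028 for Tlr2, and with voom -0.0087 for Tlr4. The decidual covariate gave 0.031 for Vegfa and -0.15 for Tlr4. The surrogate variable gave 0.016 for Vegfa, -0.016 for Eng, -0.093 for Tlr4 and 0.41 for Gcm1, and the first component as a covariate 0.019, -0.020, -0.099 and 0.40. Over single left-out libraries the values ran from -0.063 to 0.19 for Pgf, -0.21 to 0.70 for Cxcl1, -0.21 to 0.021 for Tlr2 and -0.091 to 0.15 for Tlr4.

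List means also changed sign, and the cause was not tested. The decidual covariate gave 0.050 for trophoblast giant cells, 0.00080 for labyrinth, -0.0012 for decidual stroma itself, -0.11 for macrophages, -0.054 for endothelial cells, -0.033 for Toll-like receptor genes, 0.066 for hypoxia, -0.0024 for apoptosis, -0.047 for matrix and -0.00090 for steroid hormone genes. The Y-linked covariate gave -0.015 for macrophages, -0.0029 for endothelial cells and 0.0067 for hypoxia, RLE gave -0.0012 for macrophages, and genes with any count gave 0.0025 for giant cells, 0.013 for chemokines and 0.0013 for angiogenic factors. With the first component as a covariate, and in parentheses with the surrogate variable, the means were 0.0018 (0.0017) for giant cells, 0.13 (0.12) for labyrinth, 0.0063 (0.0031) for uterine natural killer cells, -0.14 (-0.14) for macrophages, 0.069 (0.068) for lymphocytes, -0.024 (-0.023) for endothelial cells, -0.043 (-0.041) for Toll-like receptor genes, -0.035 (-0.035) for complement, 0.074 (0.072) for hypoxia, -0.0047 (-0.0037) for apoptosis, -0.033 (-0.031) for matrix, 0.040 (0.040) for imprinted genes and -0.050 (-0.049) for steroid hormone genes. Over single left-out libraries the means ran from -0.075 to 0.036 for giant cells, -0.23 to 0.074 for labyrinth, -0.15 to 0.13 for uterine smooth muscle, -0.090 to 0.10 for macrophages, -0.12 to 0.16 for lymphocytes, -0.047 to 0.043 for endothelial cells, -0.031 to 0.010 for pericytes, -0.032 to 0.089 for Toll-like receptor genes, -0.10 to 0.050 for chemokines, -0.16 to 0.015 for interferon, -0.037 to 0.11 for complement, -0.025 to 0.011 for angiogenic factors, -0.073 to 0.049 for hypoxia, -0.032 to 0.089 for matrix, -0.088 to 0.021 for imprinted genes, -0.018 to 0.064 for nutrient transporters and -0.0011 to 0.16 for steroid hormone genes.

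Over the named genes, 1434 values under an alternative kept their direction and side of the threshold, 4 gained a call (all with DESeq2) and 22 changed sign. Over the 29 lists, 394 kept both, 51 lost a call and 14 gained one with the sign kept, and 92 changed sign. With 20029190 to 27206445 counts per library, a change of 1.5-fold or more could be excluded by the 95% interval only for the 74.2% of genes named above.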

Other observations

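The tests of the decidua share, of NF-kB signalling and of other divisions of the libraries were chosen only after the results were seen, as was the use of the first principal component as a covariate.

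Placentas of both treatments differed among themselves far more than Fn differed from PBS. At the negative end of the first principal component (PBS replicates 1 to 3 and Fn replicate 1) stood genes of the syncytial labyrinth and of granulated uterine natural killer cells. Syna and Synb, the envelope genes that fuse trophoblast, ranged over the 10 libraries from 5.68 to 53.1 CPM and from 7.99 to 84.0 CPM, perforin (Prf1) from 6.22 to 124 CPM, and the granzyme gene Gzmd, one of a family of similar genes, from 44.6 to 715 CPM. At the positive end stood the oxytocin receptor Oxtr (3.30 to 65.4 CPM), the deiodinase Dio2 (6.74 to 71.3 CPM), the steroid enzyme Hsd3b1 (2.39 to 82.1 CPM), the natriuretic peptide Nppb (1.98 to 36.1 CPM) and alpha-fetoprotein (Afp, 3378 to 19564 CPM). The scores of labyrinth and natural killer cell markers followed the component with r = -0.97 and -0.94 (rho -0.98 and -0.96, adjusted permutation p for r = 0.000303 each, r = -0.94 and -0.93 without the 2 farthest libraries), whereas decidual stroma markers gave r = 0.32 (rho 0.27, adjusted permutation p = 0.361).

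Y-linked genes divided the libraries cleanly. PBS replicates 2 and 3 and Fn replicates 1 and 4 had at least 2224 Y-linked counts and the other 6 libraries at most 7, so each treatment held 2 libraries of male type and 3 of female type. Between these types edgeR called 7 genes at adjusted p under 0.05, namely Ddx3y, Uty, Kdm5d and Eif2s3y on the Y chromosome, the X-linked Eif2s3x (log2 fold change male over female -0.34) and Taf1 (-0.44), and the predicted gene Gm26992. Of 318 pathways in the deposited annotation, camera called 0 between Fn and PBS with the preset correlation (30 at an unadjusted p under 0.05, smallest adjusted p = 0.118) and 0 with an estimated one, and fry called 0. Among them, protein processing in endoplasmic reticulum (155 genes), set beside the unfolded protein list, had a mean of -0.0038 (camera adjusted p = 0.99974 with the preset correlation).

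A hypothesis for the spread along the first component is that the placentas were of different developmental stage. The share of the embryonic globins Hbb-bh1 and Hba-x among globin counts, which falls as pregnancy advances, ranged from 22.1 to 275 ppm and followed the component computed without globin genes (rho = -0.721, permutation p = 0.0228, adjusted 0.0329, r = -0.83, r = -0.69 without the 2 farthest libraries), on 3 to 61 counts per library. Fn replicate 2, the library at the positive extreme, had 72.6 ppm on 10 counts, against 70.7 ppm in PBS replicate 3 at the negative end. The share of another globin, Hbb-y, computed beside it, gave r = -0.93 and rho = -0.94 (adjusted permutation p = 0.000303 and 0.000737). It rested on 0 counts in Fn replicate 2 and 113 in PBS replicate 1. Library size had r = -0.53 and rho = -0.39 with the component (adjusted permutation p = 0.149 and 0.284). Counting depth itself is argued against, since thinning every library to the depth of the smallest left the component in place (r = 0.999984 with the original). Decidual stroma and natural killer cell markers had slopes that differed by 0.958 log2 units per SD of the component (95% intervals over members -0.10 to 0.19 and -1.23 to -0.60). This argues against a larger share of maternal decidua only if its cell make-up was constant. The intervals are over genes, not libraries, and decidual members diverged, with Prl3c1 at r = -0.98 and Prl8a2 at r = 0.45. A larger share of decidua of differing make-up stays open. Stage may account for the spread, but differences in the piece of placenta taken, in litter or in dam were not tested, and the labels used here give no day of pregnancy. With 5 libraries per treatment no correlation within a treatment is given.

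The score of the immediate early list, though not that of each gene in it, was higher in every Fn library than in any PBS library, and the design offers exposure to Fn as a biological explanation. Position along the first component is argued against as the whole cause, since the mean difference was 0.29 without and 0.269 with the component as a covariate. The 95% interval of the latter (0.15 to 0.39) is over member genes and does not measure the spread between libraries. With this covariate and an estimated correlation camera did not call the list (adjusted p = 0.294). Longer handling before freezing could also raise such genes, and it stays open: the heat shock list (6 genes, among them the near-identical Hspa1a and Hspa1b) had all 6 members higher in Fn, with Hspa8 (log2 fold change 0.17, SE 0.072) higher in every Fn library than in any PBS library and Hsph1 at 0.21 (SE 0.084), while the list score differed by 0.181 (95% interval -0.17 to 0.53, exact two-sided permutation p = 0.246), an interval that includes both 0 and the immediate early difference. Toll-like receptor and NF-kB signalling also stays open, with a list difference of 0.0175 (95% interval -0.25 to 0.28). The list call itself was lost with an estimated correlation (camera adjusted p = 0.0769), so the pattern is a hypothesis for other samples.

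Neutrophil markers were called higher in Fn by camera with the preset correlation only, with 8 of 11 members higher by edgeR's log2 fold change. They were not called by camera with an estimated correlation (adjusted p = 0.996), by fry (0.982) or by the exact two-sided permutation test (p = 0.103). Neutrophils, 1 library or epithelial cells all stay possible. Without Fn replicate 3 the mean difference was 0.433 against 0.58 with it, with a 95% interval over members of 0.085 to 0.78 that includes less than 50% of the full value, so this library as the source cannot be excluded, and Lcn2 and Ltf were highest in Fn replicates 2 and 3 together. S100a8, S100a9 and Lcn2, which epithelia also express, had a mean of 0.66. Without them the other 8 members had a mean of 0.555 (95% interval 0.012 to 1.10), too wide to decide. Of these 8, 6 were higher by the difference of mean log2 CPM, a different measure from edgeR's log2 fold change. They include Ltf (edgeR log2 fold change 1.43), which epithelia also make, so the comparison cannot separate epithelial from neutrophil expression. Both 95% intervals in this paragraph are over member genes and do not measure the spread between libraries. The most abundant members in Fn libraries were Lcn2 (84.1 CPM), Ltf (82.1 CPM) and Cxcr2 (65.1 CPM), of which Cxcr2 was not higher in Fn, and 1 of the 11 measured members is also in another list.

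The gene and list tests were repeated on 100 of the 126 possible divisions of the 10 libraries into 5 and 5, the real one included. The real division called 0 genes, so all 100 called as many by construction and that count decides nothing. The highest of the others called 2198, and 4 divisions called any gene. At an unadjusted p under 0.05 the real division had 546 genes, and 46 of the 100, itself included, had as many. Those with the most calls (476, 1942 and 2198) set PBS replicates 1 to 3 and Fn replicate 1, with 1 further Fn library, against the rest, which points to the structure along the first component. For lists, 43 of the 100 divisions, the real one included, gave as many calls by camera with the preset correlation as the 7 of the real one, with a highest other count of 17 and a median of 6, so chance cannot be excluded as the source of that count. With an estimated correlation 0 of the 100 divisions called any list, so the lack of calls does not set the real one apart. The smallest camera adjusted p with it was 0.0769 in the real division. It was 0.0597 in the division that set PBS replicates 1, 2 and 5 and Fn replicates 2 and 5 against the rest.

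Opposite responses of male and female placentas were tested as a hypothesis for the lack of calls. A fit with the Y-linked type, treatment and their interaction called 0 interaction genes by edgeR (454 at an unadjusted p under 0.05), and across 9235 genes, which are not independent replicates, the male and female log2 fold changes correlated at r = 0.037. With 2 male-type and 3 female-type libraries per treatment the test cannot decide.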
